A study of Homo sapiens and Homo sapiens
Human immunodeficiency virus 1 with 16 samples.

How the data were processed

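Total RNA was sequenced from SUPT1, a human CD4+ T cell line grown from a T cell lymphoma, in 16 libraries. Cells were mock infected, infected with HIV-1 or exposed to virions inactivated by ultraviolet light (UV virions), and collected at 12 h or 24 h. Per the labels' protocols, ribosomal RNA was depleted with a RiboMinus kit, the remaining RNA was fragmented and reverse transcribed from random hexamers, and both ends of the fragments were read on an Illumina instrument. The labels do not say whether the libraries keep strand. Per the submitters' processing notes, TopHat, Bowtie, SAMtools, HTSeq and Cufflinks were used with builds hg19 and GRCh37; no versions are given.

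The deposited table is named for RPKM, but its values are counts per gene without normalization, and they were analysed as counts. Every value is a whole number, library totals range from 1703454 to 3745786, and counts rise with gene length (Spearman rho 0.21 over 10965 protein-coding genes, a relation across genes). In the 14 pairs of replicates, the chi-square per gene was 1.07 to 1.31 for genes of 3 to 10 counts, near the value of 1 that counting alone gives. It was 1.82 to 4.26 for genes of 100 to 300 counts. The planned test assumed RPKM and used limma on log values; because the unit is counts, the test used was edgeR's quasi-likelihood test, and limma became an alternative.

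The table holds 61197 features: 57244 Ensembl genes and 3953 loci assembled by the submitters (3594 named XLOC and 359 named u_XLOC). No count was above 0 for 19296 features, among them all 49 copies of genes in the pseudoautosomal part of the Y chromosome. No feature names HIV-1, so viral RNA was not analysed here. Symbols were found for 39245 Ensembl identifiers, and a gene type from GENCODE v29 (GRCh38) for 51330; 5914 identifiers are not in that release. That release served only for names, types, lengths and GC content, and no coordinates were taken from it.

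Groups were taken from the sample titles: 3 libraries each of mock, UV virions and HIV-1 at 12 h, 3 of HIV-1 at 24 h, and 2 each (replicates 1 and 3) of mock and UV virions at 24 h. For 2 libraries, 12 h mock replicate 3 and 24 h HIV-1 replicate 3, the characteristics give the other time, while the title, source name and sample code give the time used here. By correlation of log2 CPM, 24 h HIV-1 replicate 3 was nearest to 24 h HIV-1 replicate 1 (r 0.967), and 12 h mock replicate 3 was nearest to 12 h UV replicate 3 (r 0.98). It was also the nearest library to 24 h UV replicate 3 (r 0.977), 12 h mock replicate 1 (0.978) and 12 h HIV-1 replicate 1 (0.977). These correlations alone do not settle the time of that mock library. On the second principal component it lay at 16.3, the other 12 h mock libraries at 30.9 and 34.6, and the 24 h mock libraries at -21.8 and -38.2. That position goes with the 12 h time used here. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples.

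Genes with a mean of at least 1 CPM (counts scaled to library size) over the 16 libraries were tested, 16263 in all. One edgeR quasi-likelihood model with 6 group means was fitted to all libraries with relative log expression (median of ratios) size factors, so that every comparison shared 1 estimate of the spread (common biological coefficient of variation 0.106, prior degrees of freedom 16.6). The groups were compared as HIV-1 against mock, UV virions against mock and HIV-1 against UV virions at each time, as 24 h against 12 h in mock, and as the change of the HIV-1 and UV virion effects from 12 h to 24 h. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 16263 genes; p-values are two-sided and, unless another tool is named, come from this test. Standard errors are those implied by the test, the size of the log2 fold change over the square root of F. Levels are CPM scaled by the size factors, given as mean ± SD with n of 3 for each group except 24 h mock and 24 h UV virions, where n is 2. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

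The design, the gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The rule names, for each comparison with mock or UV virions, the 8 largest changes in each direction (5 for comparisons of times) among called genes that reached a mean of 5 CPM in a group and whose groups did not overlap, leaving out small RNAs and pseudogenes. Assembled loci and genes without a symbol were left out as well, so the largest changes given below are the largest among the remaining genes. Pseudogenes were told by gene type, so RPS27AP5, typed as protein-coding, stayed in. Groups of 3 and 3 stand apart by chance for 10% of genes, groups of 3 and 2 for 20% and groups of 2 and 2 for 33.3%. It adds up to 4 members of each list discussed, those with the smallest p, and CD4, CXCR4, CDKN1A, CD69, EGR1, CCNT1, HEXIM1, MYC and GAPDH in HIV-1 against mock. For the changes of effect from 12 h to 24 h, groups that stand apart were not required.

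The lists cover interferon-stimulated genes, HIV-1 restriction factors, transcription elongation factors, p53 target genes, cholesterol synthesis, T cell activation and early response, NF-kB target genes, integrated stress and unfolded protein response, heat shock and chaperones, G2 and mitosis, G1/S and DNA replication, apoptosis regulators, splicing factors, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, hypoxia and glycolysis, T cell identity and receptors, replication-dependent histones, snoRNA host genes and nuclear noncoding RNAs, MHC and antigen presentation, and the ubiquitin ligase and degraded targets of HIV-1 accessory proteins. A further 5 lists hold markers of B cells, myeloid cells, epithelial and kidney producer cells, fibroblasts and red cells. Only 3 genes are in more than 1 list. Of the 43 histone symbols listed, 20 matched the table and 19 were tested. The 21 lists with at least 5 tested members were tested with camera (limma) at a preset correlation between genes of 0.01, with adjustment over the 21 lists of a comparison, and again with an estimated correlation.

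The model was tested on simulated counts for the real genes, with a set of genes changed by known folds. For the 12 h HIV-1 comparison (16020 genes) it recovered 31.9% of 1.5-fold, 61.2% of 2-fold and 90.3% of 4-fold changes. For the 24 h comparison (16011 genes) it recovered 15.7%, 41.9% and 72.3%. It made 4 false calls in each, among 123 and 88 calls. The simulated counts held no trend with GC content and no broad shift with expression level, while the real counts held both. These rates therefore describe the model under its own assumptions and not the real comparisons.

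The settings of that set were library totals without size factors, quantile normalization with limma, limma with pseudocounts of 0.1 and 1, no filter, a mean CPM of 5 or more, only the compared groups in the fit, the replicate number as a block, at least 1.5-fold change, the 2 libraries with conflicting times left out or given the other time, an estimated correlation for lists, and leaving out each library in turn. After the data were seen, TMM factors, DESeq2, limma with a pseudocount of 0.5, removal of a GC content and length trend from each library, and leaving out 12 h mock replicate 2, which stands apart on the third principal component, were added. The trend was fitted to protein-coding genes with splines of 4 degrees of freedom; 94.3% of tested genes had a GC value.

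The overlap of calls at 12 h and 24 h was set against genes permuted within 40 strata of mean CPM in the UV virion libraries, and within these and 5 strata of GC content; this test was chosen after the results were seen. Bounds for genes at 0 in a group were computed against 3 counts over the group, and ratios with 1 to 3 counts in a group have exact 95% intervals from the summed counts; both cover counting error only. Where the counting did not use strand, reads of overlapping and antisense genes cannot be told apart, so values of antisense RNAs are uncertain. Values of histone, ribosomal protein and other genes with near-identical copies are uncertain too.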

Results

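Host transcripts of SUPT1 cells were counted in 16 total RNA libraries, 3 each of mock, UV virions and HIV-1 at 12 h, 2 of mock and 2 of UV virions at 24 h, and 3 of HIV-1 at 24 h. The 24 h HIV-1 libraries stood far from all others. On the first principal component (36.2% of variance) they lay at 73.7 to 77.1, and the other 13 libraries at -36.2 to -4.4. Replicate 3 of HIV-1 at 24 h and replicate 3 of mock at 12 h, whose recorded times conflict, were used with the time of their column names. The former lay with the 24 h HIV-1 libraries, at 74.4, and the 12 h HIV-1 libraries lay at -11.8 to -4.4. The setting that gives both libraries their other time thus puts an unlike library into the 12 h HIV-1 group. Every comparison shares 1 estimate of the spread, so calls lost under that setting do not by themselves show that a result is fragile. The 3 libraries of HIV-1 at 24 h held 1703454 to 2044809 counts and the others 1812012 to 3745786. Protein-coding genes took 76.853% ± 0.633 of counts in HIV-1 at 24 h and 83.327% to 85.255% in the other groups. Long noncoding RNAs took 4.123% ± 0.475 in HIV-1 at 24 h and 2.345% to 2.72% elsewhere. The 10 most abundant features of each library took 14.4% to 15.76% of counts in the 24 h HIV-1 libraries and 7.27% to 10.75% in the others.

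**Figure D1:**
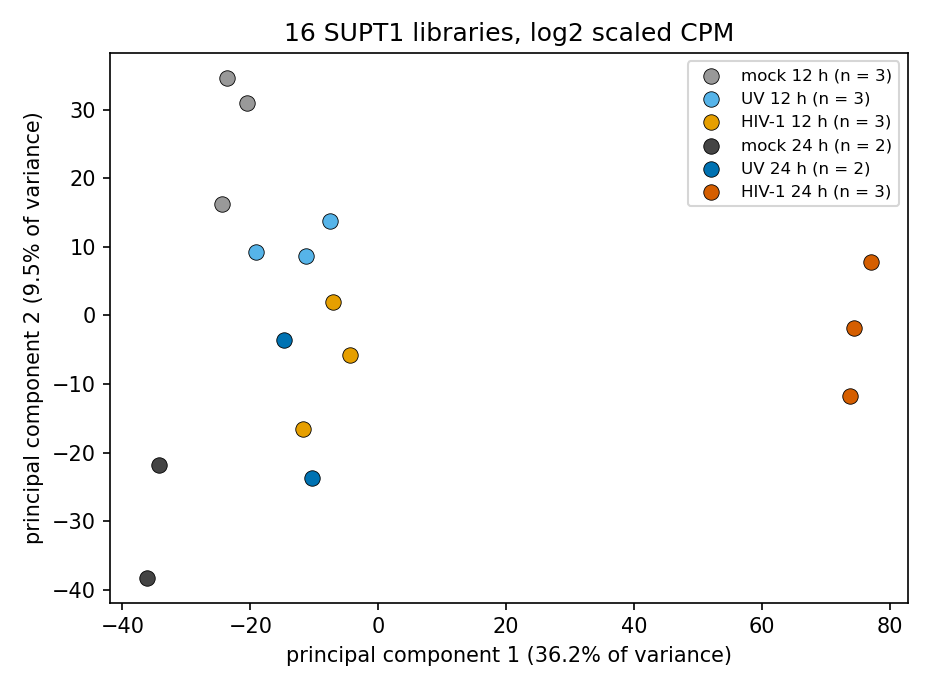
First and second principal components of log2 scaled CPM (percent of variance on the axes), with 1 point per library and a colour per group. The 3 libraries of HIV-1 at 24 h lie at 73.7 to 77.1 on the first component and the other 13 at -36.2 to -4.4.

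HIV-1 against mock at 12 h addressed which host transcripts changed early in infection. EGR1, an immediate-early transcription factor gene, rose, and MYC fell. Some genes of G2 and mitosis were lower, and some of the respiratory chain and the ribosome higher, but none of these lists passed with an estimated correlation (adjusted p = 0.20, 0.25 and 0.42). How many genes passed depended on single libraries.

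At 12 h, 1460 of 16263 genes were called between HIV-1 and mock, 652 higher and 808 lower. The count was 480 without 12 h mock replicate 1, 565 without 12 h HIV-1 replicate 2 and 688 without 12 h HIV-1 replicate 3. Higher calls made up 44.7%, and 58.6% with library totals only, 56.3% with quantile normalization and 27.7% with the GC content and length trend removed. Fold changes at 12 h rose with GC content (rho 0.44 across 8802 genes), so that genes called higher had a median GC content of 58.7% and genes called lower 42.2%. With that trend removed 1039 genes were called, 787 of them among the 1460. With only HIV-1 and mock at 12 h in the fit 914 genes were called, and with both conflicting libraries given their other time 393; that change ended 23 of the 39 called genes named here for this comparison. Only 104 higher and 59 lower genes changed at least 2-fold.

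EGR1 (ENSG00000120738.7) reached 72.5 ± 2.9 CPM in HIV-1 and 17.5 ± 6.85 in mock, a log2 fold change of 2.14 (SE 0.19, adjusted p = 1.2e-07). MYC (ENSG00000136997.10), which encodes a growth-promoting transcription factor, was at 69.8 ± 5.07 against 203 ± 54.5 CPM, a log2 fold change of -1.53 (SE 0.17, adjusted p = 4.9e-06). TERC, the RNA component of telomerase, showed the largest rise among the genes named by the rule, 9.95 ± 5.57 against 0.963 ± 0.615 CPM (log2 fold change 3.45, SE 0.62, adjusted p = 0.0012). CLEC11A, TMEM160, SCAND1 and ZNF593 were also higher, with log2 fold changes of 1.58 to 1.90. ZNF593 kept its call with the trend removed, at 1.02. The antisense RNA HMGA2-AS1, LRRC75A, TP53INP1, HS6ST1, ARHGAP19-SLIT1 and PTGDR2 were lower, with log2 fold changes of -1.51 to -1.21. The other 3 of the 16 largest changes were BCKDHA (2.00), the antisense RNA ATP2A1-AS1 (1.62) and CD2 (-1.41). Their calls were borderline and ended on leaving out any 1 of several libraries. BCKDHA had adjusted p = 0.11 without mock replicate 1, 0.06 without mock replicate 3, 0.052 without HIV-1 replicate 2 and 0.068 without HIV-1 replicate 3. ATP2A1-AS1 had 0.18, 0.066 and 0.058 without mock replicates 1, 2 and 3, and 0.17 and 0.08 without HIV-1 replicates 1 and 3; with the trend removed it had 0.17. CD2 had 0.14 without mock replicate 1, and 0.13 and 0.054 without HIV-1 replicates 2 and 3.

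Of the other genes fixed beforehand, CD4, which encodes the HIV-1 receptor, did not differ detectably at 12 h (214 ± 9.56 against 236 ± 28.5 CPM, adjusted p = 0.51). The same held for CXCR4 (adjusted p = 0.30), CD69 (0.96), CDKN1A (0.39) and CCNT1 (0.91); the sign for CD69, CDKN1A and CCNT1 depended on the processing. HEXIM1, an inhibitor of the elongation factor P-TEFb, was lower by the test (log2 fold change -0.43, adjusted p = 0.023). That call ended without mock replicate 1 (adjusted p = 0.07) and without HIV-1 replicates 1, 2 and 3 (0.075, 0.058 and 0.068). GAPDH was called higher (log2 fold change 0.37, adjusted p = 0.046), but not without mock replicates 1 and 2 (0.18 and 0.11), not without HIV-1 replicates 1, 2 and 3 (0.051, 0.19 and 0.085), and not with the trend removed (0.64).

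Among the lists at 12 h, G2 and mitosis had 15 of 30 members lower and 1 higher (17 and 1 adjusted over the list alone; median log2 fold change -0.37). camera gave adjusted p = 4.8e-10, and 0.20 with an estimated correlation. CENPF fell most of the 4 leading members, to 181 ± 31.2 from 416 ± 161 CPM (log2 fold change -1.20, adjusted p = 0.0011), followed by KIF20A (-0.79), HMMR (-0.71) and CENPE (-0.68). Splicing factors had 9 of 33 lower (15 adjusted over the list alone; adjusted p = 8.8e-08, and 0.087 with an estimated correlation). TRA2B was lower (log2 fold change -0.43), as was HNRNPU (-0.63), which had adjusted p = 0.068 without mock replicate 1. Heat shock and chaperones had 6 of 15 lower (8 adjusted over the list alone; adjusted p = 3.5e-05, and 0.20 with an estimated correlation). HSPH1 was lower (-0.49), as was HSPD1 (-0.63), which had adjusted p = 0.056 without HIV-1 replicate 2. In the T cell identity list, 9 of 37 were lower and 2 higher (9 and 4 adjusted over the list alone; adjusted p = 0.016, and 0.49 with an estimated correlation). The recombinase genes RAG1 (417 ± 34.7 against 879 ± 105 CPM, log2 fold change -1.08, adjusted p = 6.2e-05) and RAG2 (-0.88) led that list. UV virions against the same mock libraries gave like medians for G2 and mitosis (-0.33), splicing factors (-0.21) and chaperones (-0.35). In HIV-1 against UV virions at 12 h these medians were 0.07, -0.03 and -0.05 (camera adjusted p = 0.86, 0.069 and 0.80). For these lists infection, contact with virions and a deviation of the 12 h mock libraries cannot be told apart.

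Some of the lists that were higher at 12 h shrank with the GC trend removed. Nuclear-encoded oxidative phosphorylation had 14 of 51 higher and none lower (18 adjusted over the list alone; median log2 fold change 0.28, adjusted p = 5.7e-10, and 0.25 with an estimated correlation), and 8 higher with the trend removed. COX8A rose by a log2 fold change of 0.94 and NDUFA13 by 0.83. Cytosolic ribosomal proteins had 13 of 73 higher and 1 lower (17 and 3 adjusted over the list alone; adjusted p = 0.00038, and 0.42 with an estimated correlation), led by RPL27 (0.85) and RPL18 (0.80). Replication-dependent histones had 7 of 19 higher (12 adjusted over the list alone; adjusted p = 8.8e-08, and 0.25 with an estimated correlation). With the trend removed the histone list had 1 higher and adjusted p = 0.22. H3C4 was called at 0.72, but had adjusted p = 0.059 without mock replicate 1, 0.057 without HIV-1 replicate 3 and 0.59 with the trend removed. H2AC11 was called at 0.64, with adjusted p = 0.058 without mock replicate 1 and 0.06 without HIV-1 replicate 2. Cholesterol synthesis had 3 of 23 higher (4 adjusted over the list alone; adjusted p = 0.00038, and 0.31 with an estimated correlation), STARD4 among them (log2 fold change 0.45). MVD was called at 1.23 (adjusted p = 0.0068), but had 0.061 with the trend removed. T cell activation and early response had 3 of 18 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.15). DUSP5 (1.03) had adjusted p = 0.05 without mock replicate 3 and without HIV-1 replicate 2. FOS (0.91) had 0.069 and 0.084 without mock replicates 1 and 3, and 0.058 and 0.067 without HIV-1 replicates 1 and 2. The integrated stress list had 1 of 24 higher, SHMT2 at 0.50 (4 adjusted over the list alone; adjusted p = 0.0049, 0.31 with an estimated correlation and 0.11 with the trend removed). SHMT2 had 0.085 without mock replicate 1, 0.051 without HIV-1 replicate 2 and 0.059 with the trend removed. The histone list had a median of 0.42 here and 0.32 in UV virions against the same mock libraries. In HIV-1 against UV virions at 12 h its median was 0.08 (camera adjusted p = 0.80). For the histone list too, infection, contact with virions and a deviation of the 12 h mock libraries cannot be told apart.

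HIV-1 against mock at 24 h addressed the state of the cells later in infection. FOSB, FOS, JUN and ATF3 were many times higher. Genes of cholesterol synthesis rose as a group. Genes of the cell cycle and of T cell identity fell, and CD4 fell with them. The change was broad and followed expression level: weakly expressed genes tended to rise and abundant ones to fall.

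At 24 h, 7069 genes (43.5% of 16263) were called between HIV-1 and mock, 3486 higher and 3583 lower, with 2009 higher and 1334 lower by at least 2-fold. Higher calls made up 49.3%, and 62.5% with library totals only. That scaling moved the median log2 fold change of all genes from 0.078 to 0.243, and the values below are relative to the size factors. Leaving out any 1 library gave 4837 to 6437 calls. With every library thinned to 1703454 counts, 6267 genes were called, 3106 higher and 3161 lower. Fold changes at 24 h rose with gene length (rho 0.26) and fell with GC content (rho -0.17) across 8802 genes. With that trend removed, 6094 of the 7069 stayed called in the same direction.

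FOSB (ENSG00000125740.9) rose to 116 ± 7.97 from 4.75 ± 0.639 CPM, a log2 fold change of 4.61 (SE 0.24, adjusted p = 1.1e-13). ATF3 (ENSG00000162772.12) rose to 49.2 ± 5.05 from 1.8 ± 0.519 CPM (log2 fold change 4.76, SE 0.37, adjusted p = 1.1e-10). BBC3, a proapoptotic p53 target, had 84 summed counts in HIV-1 and 2 in mock, a ratio of 35.9 (interval 9.63 to 301). ADCY9 had 38 and 1, a ratio of 32.5 (5.49 to 1320). In mock MDGA1, TAS2R46, COL6A1 and FAM166A had no counts, and in HIV-1 they were at least 12-fold, 10.8-fold, 9.69-fold and 9.12-fold higher. In the other direction, CCNI2 (ENSG00000205089.3) fell to 22.4 ± 6.22 from 424 ± 20 CPM (log2 fold change -4.22, SE 0.21, adjusted p = 5.1e-14). The antisense RNA LCT-AS1 fell to 15.6 ± 1.66 from 207 ± 13.8 CPM (log2 fold change -3.73), and DOCK1 to 21.2 ± 2.29 from 210 ± 14.4 CPM (-3.31). STRA6, PLCH1, IL26 and SLC6A19 had log2 fold changes of -4.33 to -3.18. IGLL1 had 43 counts in mock and none in HIV-1, at least 16.8-fold lower.

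**Figure D2:**
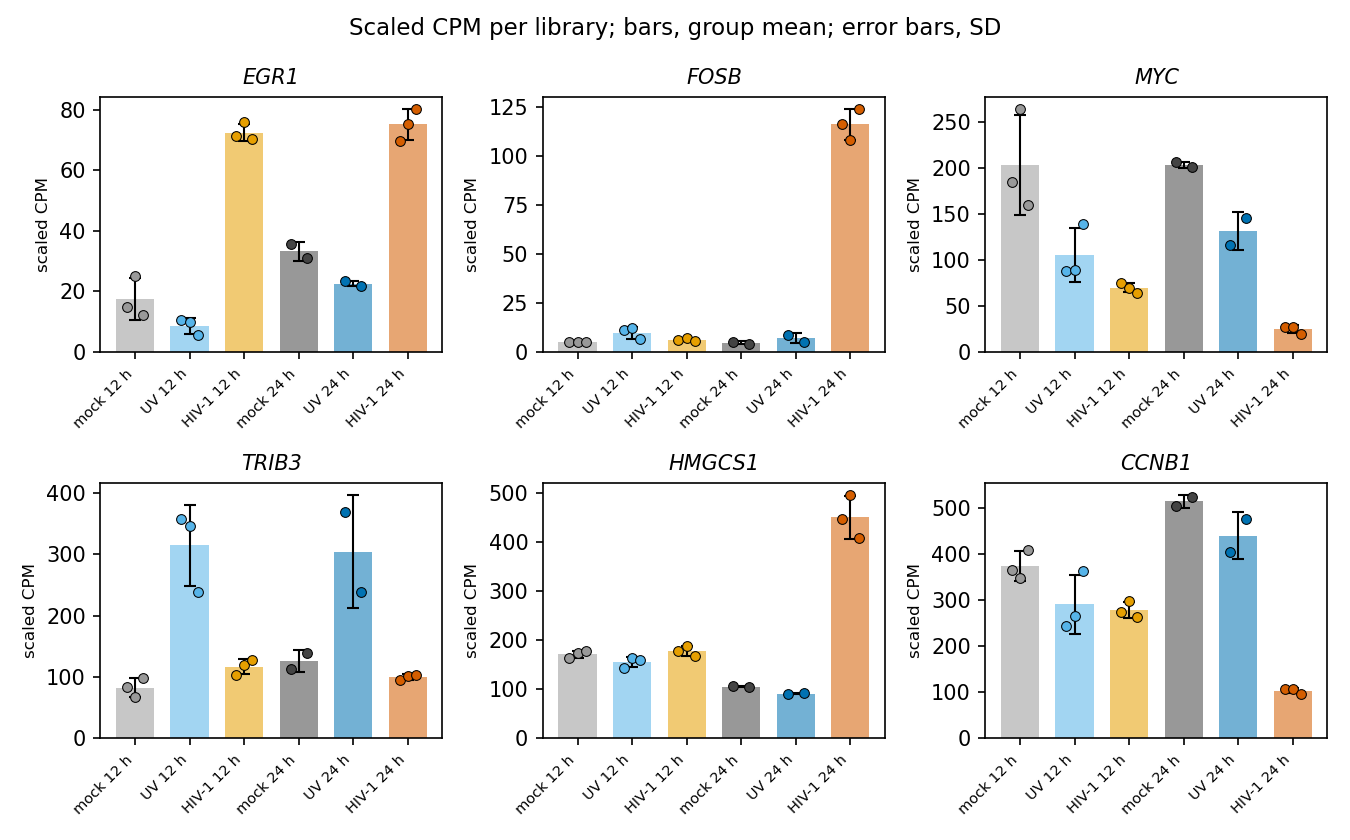
Scaled CPM of 6 genes in the 6 groups, with 1 point per library, bars for group means and error bars for SD. EGR1 was high in HIV-1 at both times, FOSB and HMGCS1 in HIV-1 at 24 h only among these groups, and TRIB3 in UV virions at both times.

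MYC fell to 24.7 ± 4.3 from 204 ± 3.34 CPM (log2 fold change -3.03, SE 0.21, adjusted p = 1.6e-11). CD4 fell to 146 ± 9.35 from 277 ± 12 CPM (log2 fold change -0.92, SE 0.13, adjusted p = 1.7e-06). EGR1 stayed higher, 75.2 ± 5.2 against 33.3 ± 3.1 CPM (1.18, adjusted p = 2.1e-05). HEXIM1 was higher, 120 ± 7.75 against 62.4 ± 6.83 CPM (0.94, adjusted p = 9e-07), and GAPDH lower, 1360 ± 253 against 2850 ± 181 CPM (-1.07, adjusted p = 2e-07). CXCR4, the coreceptor gene, was called lower (-0.67, adjusted p = 0.0012) but had adjusted p = 0.072 without mock replicate 1. CD69 was called higher (0.77, adjusted p = 0.0093) but had 0.13 without mock replicate 3. CCNT1, which encodes cyclin T1, was called lower (-0.33, adjusted p = 0.012); it had 0.094 without mock replicate 3, 0.23 with library totals only, and turned to 0.11 (adjusted p = 0.40) with quantile normalization. CDKN1A did not differ detectably (0.04, adjusted p = 0.87), and its sign changed without mock replicate 1.

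Expression level ordered the changes at 24 h. Protein-coding genes at 1 to 2 CPM in the libraries outside the comparison had a median log2 fold change of 0.95, and the 2355 at 100 CPM or more had -0.42, with 233 higher and 1358 lower. With libraries thinned to equal counts these medians were 1.01 and -0.37. The same trend ran from 0.71 to -0.37 in HIV-1 against UV virions at 24 h, and from 0.24 to -0.06 in UV virions against mock at 24 h. Of 1579 long noncoding RNAs, 434 were higher and 68 lower (median log2 fold change 0.66), against 2595 and 3060 of 11848 protein-coding genes (0.01); Fisher's exact test for higher calls gave an odds ratio of 1.35 (p = 1.1e-06). Against protein-coding genes of the nearest mean CPM over all 16 libraries, which include those compared, the difference in medians was 0.05. By level outside the comparison, long noncoding RNAs had 0.76 against 0.95 at 1 to 2 CPM and 0.70 against 0.68 at 2 to 5 CPM. They had 0.54 against 0.39 at 5 to 10 CPM and -0.16 against -0.42 at 100 CPM or more. Level thus went with much of the difference, and a smaller one remained at 5 to 10 CPM and at 100 CPM or more. Among snoRNAs and scaRNAs, 14 of 33 were higher and none lower (median 1.29; Fisher's exact test, odds ratio 2.63, p = 0.0095). Assembled loci had 138 of 513 higher and 55 lower. Pseudogenes were called less often than protein-coding genes in both directions (median -0.01). Of 1829 pseudogenes 211 were higher (11.5%, against 21.9% of protein-coding genes) and 341 lower (18.6% against 25.8%). Fisher's exact test for higher calls gave an odds ratio of 0.465 (p = 3.4e-27), which goes with fewer calls and not with a fall. Fisher's test takes genes as independent, here and above. Of these classes only the long noncoding RNAs were set against protein-coding genes of like level. Because the changes followed level, each list below is set against 10000 random lists of the same size and level, given as the percentile of its median. The random lists draw protein-coding genes independently, while genes of a real list moved together (estimated correlation 0.276 for G2 and mitosis at 24 h). Extreme percentiles thus overstate how far a list stands apart and are no p-values.

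**Figure D3:**
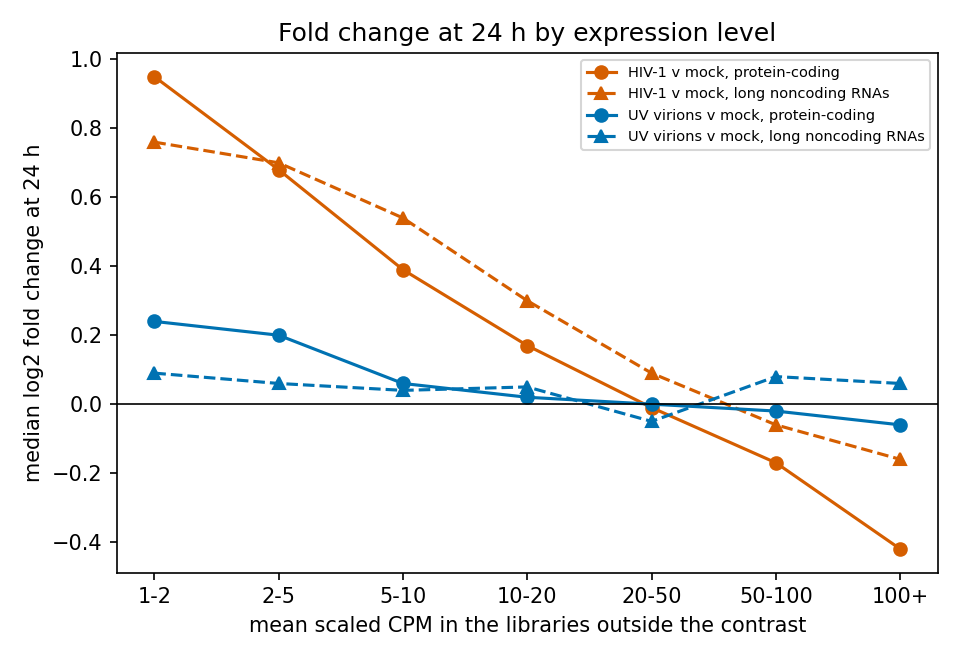
Median log2 fold change at 24 h against mean scaled CPM in the libraries outside the comparison, for protein-coding genes and long noncoding RNAs. In HIV-1 against mock the protein-coding median ran from 0.95 at the lowest levels to -0.42 at 100 CPM or more, and in UV virions against mock from 0.24 to -0.06.

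Cholesterol synthesis had 19 of 23 members higher and none lower at 24 h (19 adjusted over the list alone; median log2 fold change 0.80). camera gave adjusted p = 2e-12, and 0.039 with an estimated correlation; lists of like level had a median of -0.17, and this list lay at percentile 100. HMGCS1 (ENSG00000112972.10) rose to 451 ± 44.1 from 105 ± 1.15 CPM (log2 fold change 2.10, SE 0.12, adjusted p = 3.4e-13), followed by STARD4 (1.77) and LSS (1.75). T cell activation and early response had 8 of 18 higher and 2 lower (the same adjusted over the list alone; median 0.47, adjusted p = 0.0041, and 0.046 with an estimated correlation), at percentile 74.6 of lists of like level. JUN rose to 409 ± 47.8 from 45.2 ± 13 CPM (log2 fold change 3.16, adjusted p = 1.7e-13) and FOS to 101 ± 12.7 from 7.69 ± 0.759 CPM (3.72, adjusted p = 6.1e-12).

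G2 and mitosis had 28 of 30 members lower and none higher (28 adjusted over the list alone; median log2 fold change -1.28, adjusted p = 4e-25, and 0.025 with an estimated correlation), at percentile 0 of lists of like level, whose median was -0.38. CCNB1 fell to 103 ± 5.93 from 514 ± 13.7 CPM (log2 fold change -2.32, adjusted p = 1.2e-12). KIF20A (-2.45), PLK1 (-2.34) and CCNA2 (-2.02) fell alike. G1/S and DNA replication had 27 of 34 lower and none higher (27 adjusted over the list alone; median -0.65, adjusted p = 4.5e-11, and 0.0036 with an estimated correlation; percentile 0.36). Its leading members were RRM2 (-1.52), SLBP (-1.33), MCM4 (-1.09) and UNG (-1.75). Replication-dependent histones had 16 of 19 lower (16 adjusted over the list alone; median -0.94, adjusted p = 5.6e-09, and 0.11 with an estimated correlation; percentile 2.08), with H3C12 at -1.96 and H1-5 at -1.78.

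T cell identity and receptors had 28 of 37 lower and 2 higher (29 and 2 adjusted over the list alone; median -0.96, adjusted p = 1.1e-17, and 0.041 with an estimated correlation), at percentile 0. RAG1 fell to 123 ± 10.1 from 1020 ± 81.5 CPM (log2 fold change -3.05, adjusted p = 1.1e-13). LEF1 (-2.16), NOTCH3 (-2.50) and NOTCH1 (-2.14) followed. Heat shock and chaperones had 9 of 15 lower (9 lower and 1 higher adjusted over the list alone; median -0.82, adjusted p = 2e-06, and 0.056 with an estimated correlation; percentile 0.31). HSPA8 fell to 569 ± 56.7 from 3290 ± 114 CPM (-2.53, adjusted p = 6e-14), and DNAJA1 by -1.55. Splicing factors had 22 of 33 lower and 4 higher (23 and 4 adjusted over the list alone; median -0.58, adjusted p = 9.7e-08, and 0.032 with an estimated correlation), but lists of like level had a median of -0.49 (percentile 22.8). HNRNPF (-1.30) and SRSF7 (-1.28) led it.

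Some lists of abundant genes moved no further than level alone at 24 h. Cytosolic ribosomal proteins had 34 of 73 lower and 1 higher (the same adjusted over the list alone; median -0.36, adjusted p = 0.00019, and 0.34 with an estimated correlation; percentile 82.4). Oxidative phosphorylation had 19 of 51 lower and 6 higher (the same adjusted over the list alone; median -0.28, adjusted p = 0.038, and 0.56 with an estimated correlation; percentile 30.2); with the trend removed its adjusted p was 0.45. Hypoxia and glycolysis had 13 of 30 lower and 4 higher (the same adjusted over the list alone; median -0.23, adjusted p = 0.0059, and 0.18 with an estimated correlation; percentile 50.5). Its members went both ways, from HK2 (-2.84) and LDHA (-1.95) to ADM (3.06). Further down than most lists of like level, the list of the ubiquitin ligase and degraded targets of HIV-1 accessory proteins had 14 of 24 lower and 2 higher (15 and 3 adjusted over the list alone; median -0.49, adjusted p = 0.01, and 0.06 with an estimated correlation; percentile 3.02).

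Antiviral lists did not pass the list test at 24 h, except restriction factors with the GC trend removed (adjusted p = 0.037). Of 36 interferon-stimulated genes 7 were higher and 6 lower (the same adjusted over the list alone; median 0.53, adjusted p = 0.27; percentile 84.3). STAT2 rose (0.93, adjusted p = 2.9e-06). Of 18 restriction factors 9 were lower and 2 higher (the same adjusted over the list alone; median -0.37, adjusted p = 0.082; percentile 7.47), with TRIM28 at -1.51, SLFN11 at -0.75 and MOV10 at 0.66. MHC and antigen presentation had 3 of 17 higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.85; percentile 88.3). B2M was called lower (-0.84, adjusted p = 4.3e-06), but not with quantile normalization (-0.08, adjusted p = 0.67). NF-kB targets had 5 of 14 higher and 4 lower (the same adjusted over the list alone; adjusted p = 0.60; percentile 55.6).

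The remaining lists were mixed at 24 h. Of 23 p53 targets 8 were higher and 4 lower (the same adjusted over the list alone; adjusted p = 0.42; percentile 93.1), with BTG2 at 1.42 and AEN at -1.95. Of 25 apoptosis regulators 7 were higher and 5 lower (the same adjusted over the list alone; adjusted p = 0.55; percentile 80.9), with HRK at 2.06. Of 26 elongation factors 4 were higher and 10 lower (4 and 11 adjusted over the list alone; adjusted p = 0.32; percentile 37.9). The integrated stress list had 6 of 24 higher and 8 lower (the same adjusted over the list alone; adjusted p = 0.62). Its median was 0.20 while the test pointed down; lists of like level had a median of -0.22, and this list lay at percentile 99.5. SLC7A5 fell (-1.75). snoRNA hosts and nuclear noncoding RNAs had 7 of 23 higher and 7 lower (the same adjusted over the list alone; adjusted p = 0.22; percentile 56.6), with a median of -0.17 but a mean of 0.27 and a test that pointed up. FTX (2.18), KCNQ1OT1 (2.11) and NEAT1 (4520 ± 838 against 1390 ± 61.1 CPM) rose.

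Few markers of other cell types reached the minimum for testing. Of 8 B cell markers 3 were tested, and 2 were lower at 24 h, CD79A (14.7 ± 2.68 against 34.4 ± 0.907 CPM) and IGLL1 (the same adjusted over the list alone). Of 10 myeloid markers 1 was tested and it was not called (1 higher adjusted over the list alone). Of 10 epithelial and kidney producer markers 4 were tested, with 1 higher and 1 lower (1 and 2 adjusted over the list alone). Of 7 fibroblast markers 2 were tested and 2 were higher (the same adjusted over the list alone). Of 7 red cell markers 0 were tested.

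**Figure D4:**
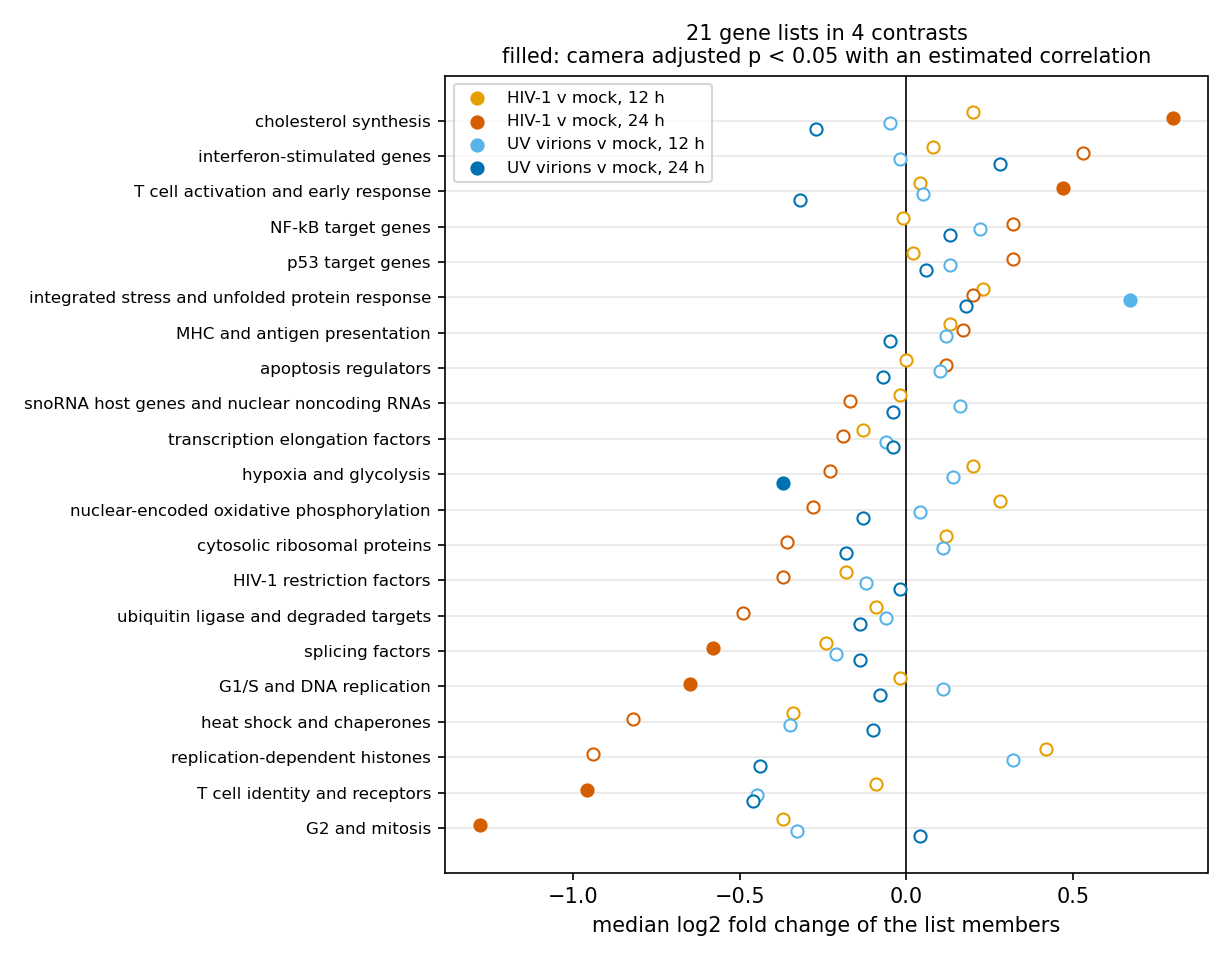
Median log2 fold change of the members of 21 gene lists in HIV-1 and UV virions against mock at 12 h and 24 h, with filled points where camera with an estimated correlation passed. In HIV-1 at 24 h cholesterol synthesis lay at 0.80 and G2 and mitosis at -1.28; in UV virions at 12 h the integrated stress list lay at 0.67.

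Comparing the effect of HIV-1 between the times addressed how infection progressed. Genes lower early were lower late more often than genes of like level. Whether genes higher early stayed higher depended on whether GC content was matched. The change of the effect was called for 4693 genes, 2016 upward and 2677 downward. It fell with GC content (rho -0.37) and rose with gene length (rho 0.37) across 8802 genes. With that trend removed, 3238 of the 4693 stayed called in the same direction.

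Of 808 genes lower at 12 h, 482 were lower at 24 h (59.7%); these comparisons share no library. Permuting genes within 40 strata of level gave 339.4 (294 to 390 in 10000 permutations, permutation test p = 1e-04). Within strata of level and GC content, for the 750 of these genes with a GC value, 459 were shared against 303.1 (265 to 346, permutation test p = 1e-04). The count was 220 of 287 without 12 h mock replicate 1, 235 of 336 without 12 h HIV-1 replicate 2 and 249 of 403 without 12 h HIV-1 replicate 3. It was 302 of 597 (50.6%) with library totals only, 237 of 478 (49.6%) with quantile normalization, 146 of 321 (45.5%) at 1.5-fold or more and 199 of 305 with both conflicting libraries given their other time. Of 652 genes higher at 12 h, 133 were higher at 24 h against 126.1 by level (permutation test p = 0.26), and 226 were lower against 208.1 (permutation test p = 0.051). With GC content matched too, 122 of 621 were higher against 78 (permutation test p = 1e-04), and 216 were lower against 251.7. The expectations thus differ with what is matched, and no excess of higher genes turning lower was shown. These permutations treat genes as independent, and 1e-04 is the smallest p that 10000 of them can give. Genes of a list moved together (estimated correlation 0.273 for G2 and mitosis at 12 h), so the ranges and p-values understate the spread. The change from 12 h to 24 h was called for 3087 genes without 24 h mock replicate 3. With both conflicting libraries given their other time 2 genes were called, and all 17 named here lost their calls; that moves 1 of the 24 h HIV-1 libraries into the 12 h group. Upward calls made up 43%, and 54.9% with library totals only, which moved the median change of all genes to 0.199 from 0.074. The effect changed upward for HMGCS1 (2.05, SE 0.15, adjusted p = 4.4e-10) and JUN (2.75, SE 0.24, adjusted p = 4.4e-09), and downward for MCM4 (-1.10) and H3C12 (-2.38). The 5 largest changes upward were in COL6A1, TAS2R46, MDGA1, ESR1 and ICA1, which had 0 or 1 count in the 24 h mock libraries and are given no fold. Downward they were in SLC6A19 (-3.75), PDXP (-3.85), MIF (-3.88), EXD3 (-4.13) and IGLL1, which had none in HIV-1 at 24 h.

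By list, the G1/S list had 25 of 34 changes downward (26 downward and 1 upward adjusted over the list alone; median -0.76, adjusted p = 3.5e-11, and 0.0021 with an estimated correlation). The histones had 17 of 19 changes downward (17 adjusted over the list alone; median -1.44, adjusted p = 8.9e-16, and 0.097 with an estimated correlation). After removal of the GC trend 11 were downward and the median was -0.68. In mock the histone list rose from 12 h to 24 h by a median of 0.32, and by 0 with that trend removed. A rise in mock enters this change with the opposite sign. Cholesterol synthesis had 12 of 23 upward (12 adjusted over the list alone; adjusted p = 9.8e-08, and 0.11 with an estimated correlation).

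UV virions against mock at 12 h addressed what contact with virions does without productive infection. The clearest response was the integrated stress response, with TRIB3, ASNS and SESN2 higher. In the T cell identity list 14 of 37 genes were lower, and the list had adjusted p = 0.067 with an estimated correlation. Most of the largest single changes were in weakly expressed genes and lost their calls without at least 1 library.

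At 12 h, 737 genes were called between UV virions and mock, 250 higher and 487 lower. The count was 257, 337 and 1339 without mock replicates 1, 2 and 3, and 182 without UV replicate 2. It was 208 with only the compared groups in the fit, 1236 without the conflicting libraries and 162 with both given their other time. Higher calls made up 33.9%, 52.5% with library totals only and 45% with quantile normalization. TRIB3 (ENSG00000101255.6), a stress-induced pseudokinase gene, rose to 314 ± 65.8 from 82.3 ± 15.5 CPM (log2 fold change 1.91, SE 0.16, adjusted p = 5.9e-08). SPNS3 rose to 56.3 ± 0.366 from 20.1 ± 3.51 CPM (1.51, adjusted p = 5.2e-05), and ATF3 to 8.41 ± 1.5 from 2.47 ± 1.35 CPM (1.73, adjusted p = 0.0063). TCF7 (-1.17), SPRY4 (-1.18), IQSEC1 (-1.39) and HIVEP3 (-1.39) were lower. The other 9 of the 16 largest were MATN4, ESRP1, RGS2, RELB and OPTN, higher by 1.44 to 1.74, and KCNA6, BTBD19, FBLN2 and LINC02454, lower at -1.76 to -1.28. Each lost its call without at least 1 library. Without mock replicate 1, MATN4 (adjusted p = 0.082), ESRP1 (0.095), RELB (0.10), OPTN (0.18), KCNA6 (0.07), BTBD19 (0.066) and FBLN2 (0.16) did. Without mock replicate 2, MATN4 (0.062), ESRP1 (0.078), OPTN (0.10), BTBD19 (0.15), FBLN2 (0.083) and LINC02454 (0.062) did, and without mock replicate 3 LINC02454 (0.057). Without UV replicate 1, ESRP1 (0.067), OPTN (0.12), FBLN2 (0.12) and LINC02454 (0.084) did. Without UV replicate 2, ESRP1 (0.16), RGS2 (0.057), RELB (0.088), OPTN (0.089), BTBD19 (0.14) and FBLN2 (0.14) did. Without UV replicate 3, MATN4 (0.055), BTBD19 (0.13) and LINC02454 (0.072) did.

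The integrated stress and unfolded protein response list had 16 of 24 members higher and 1 lower in UV virions at 12 h (17 and 1 adjusted over the list alone; median log2 fold change 0.67). camera gave adjusted p = 3.8e-29, and 0.001 with an estimated correlation. ASNS rose to 275 ± 31.4 from 113 ± 24.7 CPM (1.26, adjusted p = 2.3e-06), SESN2 to 133 ± 31.1 from 58.2 ± 2.55 CPM (1.19, adjusted p = 5.5e-05) and SHMT2 to 779 ± 91.8 from 407 ± 50.3 CPM (0.93, adjusted p = 5.6e-05). T cell identity had 14 of 37 lower (25 adjusted over the list alone; median -0.45, adjusted p = 3.2e-19, and 0.067 with an estimated correlation), led by CD3G (-0.91), GATA3 (-1.12) and RAG2 (-0.93). G2 and mitosis had 11 of 30 lower (18 lower and 1 higher adjusted over the list alone; median -0.33, adjusted p = 4.6e-13, and 0.11 with an estimated correlation), led by KIF20A (-0.93), CENPE (-0.79) and TOP2A (-0.64). Heat shock and chaperones had 4 of 15 lower (8 adjusted over the list alone; adjusted p = 4.5e-05, and 0.12 with an estimated correlation), with HSPA8 at -0.59. Histones had 6 of 19 higher (8 adjusted over the list alone; adjusted p = 5.6e-08, and 0.13 with an estimated correlation), with H2AC6 at 0.98. MYC (-0.92) was lower and JUN (0.88) higher. EGR1 was called lower (-0.94, adjusted p = 0.024), but not without mock replicates 1 and 2 (adjusted p = 0.062 and 0.15) or UV replicates 2 and 3 (0.058 and 0.12).

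UV virions against mock at 24 h repeated the question 12 h later with 2 libraries per group. Single genes of glycolysis (6 of 30) and T cell identity (9 of 37) were lower, and ATF3 and TRIB3 higher. With an estimated correlation the glycolysis list passed (adjusted p = 0.048) and the T cell identity list did not (0.12). The glycolysis list also rose in mock from 12 h to 24 h (median log2 fold change 0.43). For this list an effect of UV virions and a change of the 24 h mock libraries therefore cannot be told apart. Few calls survived the loss of a library. Leaving out a 24 h mock or UV virion library leaves a single library in its group, in this and every other comparison that uses it. A call lost in this way can come from the smaller group alone and does not show that the fold changed.

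At 24 h, 325 genes were called between UV virions and mock, 92 higher and 233 lower. The count was 121 and 20 without mock replicates 1 and 3, and 6 and 158 without UV replicates 1 and 3. It was 783 with only the compared groups in the fit, 574 without a filter, 163 with quantile normalization and 4 with both conflicting libraries given their other time. Higher calls made up 28.3%, 55.7% with library totals only and 49.1% with quantile normalization. Of the 16 largest, only CHI3L2 kept its call without any library (46.7 ± 6.02 against 109 ± 13 CPM, log2 fold change -1.21, SE 0.16, adjusted p = 0.001), as did DDIT4 (63.9 ± 6.06 against 144 ± 23.3 CPM, -1.17, adjusted p = 0.0015) among the list members. ESRP1 (2.76), ATF3 (2.71), DHRS2 (2.23), AMDHD1 (2.07), FRMD6 (1.92), OPTN (1.73), PPP1R15A (1.62) and DUSP8 (1.54) were called higher. PLEKHF1, CD69, HS6ST1, C2CD4B, HES1, NUDT8 and ASPRV1 were called lower, at -2.08 to -1.22. Without UV replicate 1 all 15 of these lost their calls, with adjusted p of up to 0.44 (DUSP8). Without mock replicate 1 AMDHD1, FRMD6, OPTN, PPP1R15A, DUSP8, CD69, HS6ST1, NUDT8 and ASPRV1 lost theirs. Without mock replicate 3 ATF3, DHRS2, AMDHD1, OPTN, PPP1R15A, DUSP8, all 7 lower genes and no others did, with adjusted p of 0.24 for PLEKHF1 and 0.17 for C2CD4B. Without UV replicate 3 FRMD6, OPTN, PLEKHF1, HS6ST1, C2CD4B, NUDT8 and ASPRV1 did.

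Hypoxia and glycolysis had 6 of 30 lower in UV virions at 24 h (13 adjusted over the list alone; median -0.37, adjusted p = 5.1e-10, and 0.048 with an estimated correlation). LDHA (-0.71), HK2 (-0.91), PDK1 (-0.80) and PGAM1 (-1.03) were lower. T cell identity had 9 of 37 lower (21 adjusted over the list alone; median -0.46, adjusted p = 1.1e-15, and 0.12 with an estimated correlation), NOTCH1 (-0.76), CXCR4 (-0.79) and CD1E (-0.80) among them. TRIB3 was called higher (1.27), DDIT3 higher (1.12) and INSIG1 lower (-0.96). Without UV replicate 1 none of these 10 genes was called, with adjusted p = 0.11 for TRIB3 and INSIG1, 0.14 for PDK1, 0.19 for DDIT3 and LDHA, 0.21 for HK2 and NOTCH1, 0.25 for CXCR4, 0.26 for PGAM1 and 0.31 for CD1E. Without mock replicate 1 LDHA, HK2, PDK1, PGAM1, CXCR4 and CD1E lost their calls as well, without mock replicate 3 DDIT3, PDK1, PGAM1, NOTCH1 and CD1E, and without UV replicate 3 PDK1 and NOTCH1. LDHA, HK2, PDK1, NOTCH1 and CD1E also lost theirs with quantile normalization.

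The change of the UV virion effect from 12 h to 24 h was called for 46 genes, 5 upward and 41 downward. Upward calls made up 10.9%, and 31.2% with the GC content and length trend removed. No library could be left out without moving this count or some of its calls. It was 27, 25 and 204 without 12 h mock replicates 1, 2 and 3, 76 without 12 h UV replicate 3, 70 and 2 without 24 h mock replicates 1 and 3, 17 without 24 h UV replicate 1, and 0 without 24 h UV replicate 3, where edgeR gave 1384 genes an unadjusted p under 0.05. The largest changes were in ARHGAP18 (1.60), HMMR (0.87) and CENPE (0.83) upward, and DDIT4 (-1.48), H2AC6 (-1.39), PGAM1 (-1.34), MZT2A (-1.33), PCLAF (-1.33), ATP1B3 (-0.84) and CORO1A (-0.72) downward. ASNS (-1.09), SHMT2 (-0.97) and H3C12 (-1.32) fell too. None of these 13 kept its call without 24 h UV replicate 3, with adjusted p = 0.11 for DDIT4, 0.15 for H3C12 and 0.24 for ARHGAP18. Of the lists, integrated stress (3 of 24 downward, 12 downward and 1 upward adjusted over the list alone; median -0.45, adjusted p = 5.2e-11) passed with an estimated correlation (0.027). So did glycolysis (1 of 30 downward, 13 adjusted over the list alone; 0.027), histones (4 of 19, 10 adjusted over the list alone; 0.036) and G1/S (0 of 34, 2 adjusted over the list alone; 0.036). The rise of the glycolysis list in mock from 12 h to 24 h (median log2 fold change 0.43) enters its change with the opposite sign. So does that of the histone list in mock (0.32). With the GC trend removed the histone list had a median of 0 in mock and -0.50 for the change of the UV effect.

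HIV-1 against UV virions at 12 h addressed which early changes go with replicating virus rather than with contact. EGR1 was higher with HIV-1, and the integrated stress genes TRIB3, ATF5 and ASNS were lower. Much of the rest followed GC content.

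At 12 h, 1077 genes were called between HIV-1 and UV virions, 498 higher and 579 lower. The count was 571 and 427 without UV replicates 1 and 2, and 377 and 388 without HIV-1 replicates 2 and 3. It was 199 with both conflicting libraries given their other time, where GADD45B turned to 0.63. Fold changes rose with GC content (rho 0.54 across 8802 genes); with the trend removed 514 genes were called, 399 of them among the 1077, and higher calls went from 46.2% to 35.4%. EGR1 was at 72.5 ± 2.9 against 8.66 ± 2.71 CPM (log2 fold change 3.08, SE 0.20, adjusted p = 1.3e-10), and TSPOAP1 at 157 ± 20.6 against 60 ± 8.71 CPM (1.38, adjusted p = 1.9e-08). KCNA6 (1.32) and CRELD2 (1.27) were higher too. ATF5 was at 130 ± 1.65 against 358 ± 38.9 CPM (-1.46, adjusted p = 3.1e-09), TRIB3 at 117 ± 12 against 314 ± 65.8 CPM (-1.42, adjusted p = 4.1e-06) and GADD45B at 3.58 ± 1.67 against 10.9 ± 1.22 CPM (-1.60, adjusted p = 0.003). The other 9 of the 16 largest lost their calls without at least 1 library. C12orf60 (1.47), NAPRT (1.39), CLEC11A (1.30) and LINC00861 (1.27) were called higher. TGFA (-1.28), YPEL4 (-1.29), FAM222A (-1.40), ESRP1 (-1.46) and RELB (-1.47) were called lower. Without HIV-1 replicate 3 all 9 lost theirs, with adjusted p of 0.11, 0.15, 0.12, 0.086, 0.19, 0.23, 0.14, 0.12 and 0.059 in that order. Without HIV-1 replicate 2 all but TGFA did (0.058 to 0.17). Without UV replicate 2 all but LINC00861 did (0.063 to 0.21), and without UV replicate 1 NAPRT (0.073), CLEC11A (0.084), LINC00861 (0.11), TGFA (0.093), FAM222A (0.21) and ESRP1 (0.087). Without HIV-1 replicate 1 TGFA (0.05), FAM222A (0.078) and ESRP1 (0.067) did. With the trend removed NAPRT (0.20), CLEC11A (0.18) and ESRP1 (0.069) were not called.

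The integrated stress list had 12 of 24 lower and 1 higher with HIV-1 than with UV virions at 12 h (16 and 3 adjusted over the list alone; median -0.51, adjusted p = 7.3e-14, and 0.02 with an estimated correlation). ASNS (-1.03, adjusted p = 3.3e-05), SLC7A11 (-0.80) and PSAT1 (-0.76) were lower. T cell identity had 11 of 37 higher (16 adjusted over the list alone; adjusted p = 1.9e-08, and 0.15 with an estimated correlation), led by CD7 (1.21) and NOTCH3 (0.72). Cholesterol synthesis had 7 of 23 higher (8 adjusted over the list alone; adjusted p = 8.8e-07, and 0.15 with an estimated correlation), STARD4 (0.44) and LSS (0.57) among them. Oxidative phosphorylation had 12 of 51 higher (18 adjusted over the list alone; adjusted p = 2e-08, and 0.20 with an estimated correlation), with CYC1 at 0.57 and COX8A at 0.64. With the trend removed NOTCH3 (adjusted p = 0.079), LSS (0.14), CYC1 (0.30) and COX8A (0.085) were not called. LSS was not called without UV replicate 1 (0.063) or HIV-1 replicate 2 (0.074), nor COX8A without HIV-1 replicate 2 (0.054).

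HIV-1 against UV virions at 24 h addressed which late changes go with replicating virus; it uses the same HIV-1 libraries as HIV-1 against mock. FOSB, FOS and JUN were higher, as were genes of cholesterol synthesis. Cell cycle genes and MYC were lower.

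At 24 h, 5593 genes were called between HIV-1 and UV virions, 2644 higher and 2949 lower. Higher calls made up 47.3%, and 55.9% with library totals only, where the majority was higher. The count was 3686 without UV replicate 3 and 3030 with both conflicting libraries given their other time. FOSB was at 116 ± 7.97 against 6.95 ± 2.53 CPM (log2 fold change 4.09, SE 0.23, adjusted p = 8e-13) and FOS at 101 ± 12.7 against 8.42 ± 1.32 CPM (3.56, adjusted p = 1.4e-11). Genes with 2 or 3 counts in UV virions had ratios of 21.7 (LINC01790, interval 5.67 to 184), 20.6 (FRAS1, 6.75 to 102), 19.4 (MAF, 5.04 to 165), 16.1 (the antisense RNA ATXN1-AS1, 4.15 to 138), 14.8 (FAM166A, 3.76 to 127) and 14.3 (SOX6, 3.64 to 123). CCNI2 was at 22.4 ± 6.22 against 226 ± 67.3 CPM (-3.32, adjusted p = 9.3e-12) and LCT-AS1 at 15.6 ± 1.66 against 162 ± 49.6 CPM (-3.38, adjusted p = 6.1e-12). IL26, MYMX, STRA6, HES5 and PLCH1 were lower, at -3.18 to -2.60. SLC6A19 was called at -2.97, but had adjusted p = 0.067 without UV replicate 3.

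Cholesterol synthesis had 18 of 23 higher in HIV-1 than in UV virions at 24 h (20 adjusted over the list alone; median 1.16, adjusted p = 3.7e-26, and 0.0052 with an estimated correlation; percentile 100). HMGCS1 (2.31), STARD4 (2.22) and INSIG1 (2.17) led it. G2 and mitosis had 29 of 30 lower (29 adjusted over the list alone; median -1.34, adjusted p = 2.3e-36, and 0.0052 with an estimated correlation; percentile 0), with CCNA2 at -1.97 and CCNB1 at -2.09. G1/S had 26 of 34 lower (30 adjusted over the list alone; adjusted p = 1.3e-11, and 0.0018 with an estimated correlation; percentile 0.69), with RRM2 at -1.83. T cell activation had 10 of 18 higher and 2 lower (11 and 3 adjusted over the list alone; median 0.84, adjusted p = 3.1e-06, and 0.0064 with an estimated correlation), at percentile 99.9 of lists of like level, with JUN at 2.72 and MYC at -2.40. Splicing factors had 18 of 33 lower and 4 higher (19 and 4 adjusted over the list alone; adjusted p = 6.5e-06, and 0.049 with an estimated correlation), no further than lists of like level (percentile 53.3), with HNRNPF at -1.14. Restriction factors had 7 of 18 lower and 1 higher (8 and 1 adjusted over the list alone; median -0.39, adjusted p = 0.039, and 0.088 with an estimated correlation; percentile 1.7). T cell identity had 20 of 37 lower and 3 higher (22 and 3 adjusted over the list alone; adjusted p = 6.4e-09, and 0.15 with an estimated correlation; percentile 0), with RAG1 at -2.39.

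Mock at 24 h against mock at 12 h showed what changed in culture without virus. Of the glycolysis list 9 of 30 genes rose, and of the chaperone list 6 of 15 fell. With an estimated correlation the former passed (adjusted p = 0.025) and the latter did not (0.095). Most of the gene calls named for this comparison ended without 24 h mock replicate 3, which leaves a single library of 24 h mock. The list tests were not repeated with single libraries left out.

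Between the mock groups 852 genes were called, 560 higher and 292 lower at 24 h. Without 24 h mock replicate 3 the count was 16, and without 12 h mock replicate 1 it was 378. It was 476 with only the compared groups in the fit. With both conflicting libraries given their other time it was 0, where edgeR gave 1644 genes an unadjusted p under 0.05. Fold changes rose with GC content (rho 0.57 across 8802 genes); with the trend removed 335 genes were called, and higher calls went from 65.7% to 51%. Hypoxia and glycolysis had 9 of 30 higher (16 adjusted over the list alone; median 0.43, adjusted p = 1e-10, and 0.025 with an estimated correlation), and 3 higher with the trend removed. PFKL (1.05), GAPDH (0.65) and ALDOA (0.63) rose. Heat shock and chaperones had 6 of 15 lower (10 adjusted over the list alone; adjusted p = 1.6e-07, and 0.095 with an estimated correlation), with HSPH1 at -0.73 and HSP90AB1 at -0.68. The largest changes were in AK4 (2.76, SE 0.44, adjusted p = 0.00067), PDXP (2.30), ZNF593 (1.98), FOXO6 (1.94) and HNRNPCL1 (1.86) upward, and LRRC4 (-1.95), RPS27AP5 (-1.88), HRNR (-1.87), ANGPT2 (-1.60) and ACSBG1 (-1.59) downward. Of these 15 genes AK4 and ZNF593 kept their calls without any 1 library. The other 13 lost theirs without 24 h mock replicate 3, with adjusted p from 0.059 (HSPH1) to 0.42 (ACSBG1). Without 12 h mock replicate 1 FOXO6, HNRNPCL1, ACSBG1 and HRNR lost theirs too, without 12 h mock replicate 2 HNRNPCL1, ACSBG1, RPS27AP5 and LRRC4, and without 24 h mock replicate 1 ACSBG1, HRNR, RPS27AP5 and LRRC4. With the trend removed PDXP (adjusted p = 0.053), FOXO6 (0.10), HNRNPCL1 (0.053), ACSBG1 (0.058), RPS27AP5 (0.061), PFKL (0.065) and GAPDH (0.12) were not called.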

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

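GAPDH, ZNF593 and HEXIM1 changed in opposite directions at 12 h and 24 h in HIV-1 against mock, with the difference itself tested; the values with the GC content and length trend removed and the expectations by level and GC content were chosen only after the result was seen. GAPDH went from a log2 fold change of 0.37 (adjusted p = 0.046) at 12 h to -1.07 (adjusted p = 2e-07) at 24 h, a difference of -1.44 (SE 0.17, adjusted p = 7.6e-07). With the trend removed the difference was -0.91 (adjusted p = 8.3e-05) and the 12 h value 0.10 (adjusted p = 0.64), so the rise at 12 h was not called. ZNF593 went from 1.58 (adjusted p = 0.00035) to -1.26 (adjusted p = 0.00018), a difference of -2.83 (SE 0.35, adjusted p = 8.7e-07). Its difference with the trend removed was -1.72 (adjusted p = 0.00014), and the 12 h value stayed called at 1.02 (adjusted p = 0.0047). HEXIM1 went from -0.43 (adjusted p = 0.023) to 0.94 (adjusted p = 9e-07), a difference of 1.36 (SE 0.17, adjusted p = 1.2e-06). The difference was 1.51 (adjusted p = 1.3e-07) with the trend removed. The 12 h call of HEXIM1 ended without any of 4 libraries and turned to 0.10 with both conflicting libraries given their other time, and that of GAPDH ended without any of 5. The mock groups moved too: from 12 h to 24 h ZNF593 rose to 30.4 from 8 CPM (log2 fold change 1.98, adjusted p = 9.1e-05) and GAPDH by 0.65 (adjusted p = 0.0037). The rise of GAPDH in mock was not called with the trend removed (adjusted p = 0.12) or without 24 h mock replicate 3 (0.17), so how far mock accounts for its difference is open. Such opposite changes with a called difference were found for 273 genes with HIV-1, 226 of them higher and then lower, and for 2 genes with UV virions. By level alone 208.1 genes would be higher and then lower and 127.6 lower and then higher. With GC content matched too, 216 were higher and then lower against 251.7, and 41 lower and then higher against 133.6.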

How the results depend on the processing

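TMM factors, DESeq2, limma with a pseudocount of 0.5, removal of the GC content and length trend and leaving out 12 h mock replicate 2 were chosen only after the results were seen. Of 5379 values for 261 gene effects under other settings, 4841 kept call and direction, 517 were weaker and 21 turned direction. Giving both conflicting libraries their other time weakened 122 and leaving out 1 library 255. The cause was not tested, except that the other times put 1 library of each of 2 groups into a group of the other time.

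Counts of called genes moved by over 1.5 times as follows. With only the compared groups in the fit, HIV-1 against mock at 12 h gave 914, UV virions against mock 208 at 12 h and 783 at 24 h, the mock times 476 and the change of the UV effect 16. With both conflicting libraries given their other time, HIV-1 against mock at 12 h gave 393, UV virions against mock 162 and 4, HIV-1 against UV virions 199 and 3030, the mock times 0 (edgeR, 1644 genes with unadjusted p under 0.05), the change of the HIV-1 effect 2, that of the UV effect 0 (1399 genes) and the overlap of 12 h and 24 h 199. Without those libraries UV virions against mock at 12 h gave 1236 and the change of the UV effect 161. At 1.5-fold or more, HIV-1 against mock at 12 h gave 703, UV virions against mock 388, HIV-1 against UV virions 442 and the overlap 146. Quantile normalization gave 163 for UV virions against mock at 24 h, 29 for the change of the UV effect and 237 for the overlap. Library totals gave 302 for the overlap. No filter gave 574 for UV virions at 24 h and 217 for the change of the UV effect, and a pseudocount of 0.1 gave 30 for the latter. Removing the GC trend gave 514 for HIV-1 against UV virions at 12 h and 335 for the mock times. Without 12 h mock replicate 2 UV virions at 12 h gave 337 and the change of the UV effect 25.

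Leaving out 1 library gave 480 to 1698 calls for HIV-1 against mock at 12 h, 4837 to 6437 at 24 h, 182 to 1339 and 6 to 158 for UV virions against mock, 377 to 1085 and 3686 to 5072 for HIV-1 against UV virions, 16 to 1013 for the mock times, 3087 to 4828 for the change of the HIV-1 effect, 0 to 204 for that of the UV effect and 220 to 474 for the overlap. Single libraries also gave 565 and 688 (HIV-1 against mock at 12 h), 257 and 337 (UV virions at 12 h), 121 and 20 (at 24 h), 571, 427 and 388 (HIV-1 against UV virions at 12 h), 378 (mock times), 27, 25, 76, 70, 2 and 17 (change of the UV effect) and 235 and 249 (overlap).

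Of 189 list tests 86 passed, 20 with an estimated correlation, 86 without the conflicting libraries (84 of them among the first 86), 78 with the GC trend removed (70 among them), 82 with library totals and 84 with the replicate block. Replicate numbers did not pair the libraries (36 pairs, median r 0.04, 13 over 0.1); among counts of genes the block moved only the change of the UV effect by over 1.5 times, to 70, and it ended 2 list calls and the call of NUDT8 in UV virions against mock at 24 h.

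The direction turned for CD69 at 12 h in HIV-1 against mock (0.01 with library totals, 0.08 quantile, 0.13, 0.12 and 0.12 with limma at pseudocounts of 0.1, 0.5 and 1, 0.35 without the conflicting libraries, 0.62 with their other time, 0.01 with the GC trend removed, 0.35 without mock replicate 3, 0.05 without HIV-1 replicate 3; -0.22 to 0.35 leaving out 1 library). It turned for CCNT1 at 12 h (0.02 with library totals, 0.09 quantile, 0.02 without the conflicting libraries, 0.07 with the GC trend removed, 0.02 without mock replicate 3, 0.01 without HIV-1 replicate 3; -0.09 to 0.02 leaving out 1 library) and at 24 h (0.11 quantile). It also turned for CDKN1A (-0.01 at 12 h with the GC trend removed, -0.06 at 24 h without mock replicate 1, up to 0.15 without replicate 3), HEXIM1 at 12 h (0.10) and GADD45B in HIV-1 against UV virions at 12 h (0.63), both with the other times.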

Other observations

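The tests of the GC content and length trend and of single mock libraries on the 12 h lists, and of a deviation of the 12 h mock libraries, were chosen only after the result was seen; the tests on long noncoding RNAs and the splits were fixed before. In HIV-1 against mock at 12 h, 14 of 51 oxidative phosphorylation, 13 of 73 ribosomal protein and 7 of 19 histone genes were higher, and none of these lists passed with an estimated correlation (adjusted p = 0.25, 0.42 and 0.25). With the GC trend removed, the 14 oxidative phosphorylation genes had a median of 0.40 (0.63 before, 7 stayed called). The 13 ribosomal protein genes had 0.51 (0.69 before, 11 stayed called). These genes were picked as called higher in the same comparison, which favours values that stay above a trend. Their medians therefore cannot decide how much of the rise the trend explains. Over the whole lists the medians went from 0.28 to 0.21 and from 0.12 to 0.03, which leaves the trend open for the ribosomal protein list. The 7 histone genes fell to 0.13 (0.52 before) and 1 stayed called; their quartiles of 0.02 to 0.40 leave open whether the trend explains them. Without mock replicate 2 the 34 genes had a median of 0.59 (0.64 before) and 21 stayed called, so their median did not depend on that library alone. The genes had been picked as called with that library in the fit. Mock replicate 1, without which the comparison called 480 genes, was not tested in this way.

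Long noncoding RNAs were higher than protein-coding genes in HIV-1 against mock at 24 h by a difference in medians of 0.65. The difference was 0.63 with every library thinned to equal counts, so unequal depth does not explain it. With the GC content and length trend removed it was 0.85. That trend was fitted to protein-coding genes of at least 10 CPM, while 488 long noncoding RNAs lay at 1 to 2 CPM and 485 at 2 to 5 CPM outside the comparison. Its removal therefore cannot decide whether GC content or length plays a part. Against protein-coding genes of the nearest mean CPM, the difference was 0.05 (-0.03 to 0.13 with 2 bootstrap SDs either side). That mean was taken over all 16 libraries, which include those compared. By level outside the comparison, long noncoding RNAs had 0.76 against 0.95 at 1 to 2 CPM, but 0.54 against 0.39 at 5 to 10 CPM. Low level thus went with much of the difference, and whether it accounts for all of it is open. Why weakly expressed genes rose and abundant ones fell was not tested.

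Integrated stress genes were higher in UV virions against mock at 12 h. The 16 members called higher, picked from this same comparison, had a median of 0.82, 0.80 with the GC trend removed and 0.81 without mock replicate 2. Against UV virions, HIV-1 libraries had a list median of -0.51, so a deviation of the 12 h mock libraries cannot be the only cause of the rise. Against the same mock libraries HIV-1 had a list median of 0.23, so such a deviation may still supply a part of it.

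Of the 10 splits of the 6 libraries into groups of 3, only the real split called as many genes (1 of 10) in each 12 h comparison. HIV-1 against mock gave 1460 and the highest other split 2, UV virions against mock 737 and 21, and HIV-1 against UV virions 1077 and 9. With 10 splits no share under 0.05 can be reached.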
